A study of Rattus norvegicus with 42 samples.

How the data were processed

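The samples were total RNA of 4 tissues of male Sprague Dawley rats, an outbred laboratory strain, combined in 2 fixed recipes and hybridised to expression arrays, 1 array per sample. Per the labels' protocols, RNA was extracted with RNeasy maxi columns and biotin-labelled cRNA was made with the Enzo BioArray HighYield kit. The labels name 21 samples as Mix 1 and 21 as Mix 2, and all 42 were used. They do not say whether the arrays of a mix came from separate pools or from repeated labelling of 1 pool, so p-values measure only the spread between these arrays, which may be technical. Whether the parts of the recipe were measured as RNA mass is not given in the sources used here.

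The deposited values are intensities on a linear scale in a single table of 31099 rows and 42 columns, from 0.0427 to 58200. In every column the mean after trimming 2% from each end was 500, so the authors had scaled each array to that target. The signal algorithm, software and detection calls are not given in the sources used here. Arrays give no read depth, and the number of arrays limits the precision. Array medians spanned 1.41-fold, above the limit of 1.25-fold set beforehand, so arrays were to be scaled to 1 trimmed mean, which left the deposited values as they were. Values below the 5th percentile of all values, 8.18, were set to it, and log2 was taken. The 57 control rows (AFFX) and the lowest 40% of the other rows by mean log2 value were left out of the tests across rows, which left 18625 rows.

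Rows were compared between mixes with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) and Benjamini-Hochberg adjustment, with a threshold of 0.05. The same fit was tested one-sided against the testes ratio of the recipe, 2.00 on the log2 scale, and against the brain ratio, -1.00, because a linear mixture of the 4 tissues lies between these before any difference in scaling. A slope per 1000 of the number in each sample's title was fitted with mix as a covariate, in each mix alone, and as an interaction. That number is the only label that orders the arrays, and no label says that it marks time. The place of an array in this order within its mix ran from 1 to 21. Gene list means and log2 ratios of 3' over 5' control rows were compared by two-sided permutation tests with 100000 resamples, whose smallest p is 1e-05. Lists were also tested with camera (preset and estimated correlation) and fry. Bootstrap intervals drew arrays with replacement 1000 times and hold the central 95% of the draws.

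The 13 gene lists were fixed before the data were examined, with 1 row per gene, that of the highest mean. The platform annotation gives 1 gene symbol for 20832 rows, several for 436 and none for 9831. Rows that the annotation assigns to the same gene differed from each other as unrelated rows do. Some sets of control rows whose own IDs name the same transcript also differed from each other (values in the report). For that reason no row is presented as a measurement of a gene. The rule fixed beforehand would have named the 3 highest members of each list and the 5 largest changes each way among rows with 1 symbol; in its place the 2 largest rises and 2 largest falls among rows whose mixes did not overlap are given without a name. The marker rows used to examine the IDs were chosen after the values were seen, as was the span of the central 99% of the differences.

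The fits were tested on simulated data with 50 rows changed per size among 18625. For the comparison of the mixes, 32% of rows changed by 0.2 on the log2 scale were recovered, 96% at 0.5, 98% at 1 and 100% at 2, with 6 false calls. In the data 85.9% of rows were called. With so few rows changed in the simulation, the adjusted threshold was stricter there, so these shares do not describe the real comparison. For the slope, 14% were recovered at 0.02 per 1000 of the title number, 64% at 0.05, 94% at 0.1 and 100% at 0.2, with 5 false calls; the simulated arrays were independent, which the arrays of a place were not. For the difference in slope these shares were 0%, 4%, 62% and 94%, with 3 false calls.

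Alternatives set beforehand were median scaling, quantile normalization, the deposited scaling, centring on the kidney list, other filters and floors, each array left out, the place as a block, the title number as a covariate, each 7 places of the order, and limma without the trend. Leaving out the arrays that stand apart and averaging the 2 arrays of a place were added after seeing the data.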

Results

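RNA of rat liver, kidney, testes and brain was combined in 2 recipes to serve as process controls for rat arrays. Mix 1 held these tissues in 3, 2, 1 and 4 parts, and Mix 2 in 2, 2, 4 and 2 parts. A transcript found in a single tissue would therefore have a log2 ratio of Mix 2 over Mix 1 of -0.58 for liver, 0.00 for kidney, 2.00 for testes and -1 for brain. Each mix was measured on 21 arrays. The median intensity per array was 223 ± 7.09 (SD, n = 21) in Mix 1 and 191 ± 8.64 (SD, n = 21) in Mix 2, a difference larger than the spread between arrays (two-sided permutation test, p = 1e-05, the smallest these permutations give).

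Rows whose IDs name 1 gene did not have like values, and this limits every statement about a gene. Among 2401 pairs of tested rows listed under 1 gene symbol, the difference between the mixes correlated across pairs at r = -0.02, where shuffled IDs gave -0.04 to 0.04 (95% of 1000 shuffles). The mean levels of these pairs correlated at 0.02, also inside the range of shuffled IDs (-0.04 to 0.04). Rows are not independent replicates. Rows listed under 8 marker genes, chosen after the values were seen, went both with and against the recipe. By mean level they ranked between 4786 (Alb) and 27562 (Tnp1) of 31099 rows, where rank 1 is the brightest. The row listed under Mbp, a myelin protein of brain, went from an intensity of 776 ± 124 in Mix 1 to 1108 ± 105 in Mix 2 (SD, n = 21 each), a log2 difference of 0.53 where a brain transcript would have -1, and that under Snap25, a protein of synapses, differed by 0.38. The log2 difference was -0.21 for Alb and -0.88 for Apoa1, both products of liver (recipe -0.58), 0.72 for Prm1 and -0.69 for Tnp1, both of spermatids (recipe 2.00; the Tnp1 row was too dim for the tests), and -0.85 for Umod and -0.13 for Kap, both of kidney (recipe 0.00). Control rows whose own IDs name 1 transcript were compared by their difference between mixes rather than by their level. That difference can still depend on the level of a row. The sets for dap and for cre were apart in level by 1.99 and 2.19 on the log2 scale. Those for phe, thr, bioC and bioD were further apart in level (6.98, 6.58, 4.84 and 4.29), and those for lys and bioB less so (1.28 and 0.91). The 2 sets of rows named for dap differed between mixes by 1.28 and -0.01, apart by 1.28 (SE 0.08, permutation adjusted p = 8e-05), and the 2 sets for cre were apart by -0.37 (SE 0.09, permutation adjusted p = 0.00132). The other 6 of 8 control transcripts did not pass this test. It was weak for bioB, lys and thr (SE 0.33, 0.35 and 0.27), and the first phe set lay near the floor (mean log2 level 3.25). Within the 2 dap sets the rows were close, at 1.21 to 1.34 and -0.02 to 0.01. Those of the first bioD set ran from -0.45 to -0.05. Control rows of 1 set were not compared with shuffled rows. The values themselves were repeatable, since the differences between mixes from odd and from even places in the title order correlated at 0.98 across rows.

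The comparison of the mixes asked how many rows the change of recipe moved. Of 18625 rows, 5907 were higher in Mix 2 and 10098 lower (limma, adjusted p under 0.05), together 85.9% of rows. With a change of at least 1.5-fold, 3039 were higher and 4507 lower. The split between higher and lower depends on scaling: median scaling gave 7945 higher and 7228 lower, and moved the median difference of all rows from -0.21 to 0.02. In 2556 rows every Mix 2 array lay above every Mix 1 array, and in 3122 every one lay below. Among those rows the largest rise was from 8.31 ± 0.48 to 10.67 ± 0.19 (log2, SD, n = 21 each), a difference of 2.36 (SE 0.11, limma adjusted p = 8.53e-25). The next rose by 2.28 (SE 0.17, limma adjusted p = 1.42e-16). The largest fall was -1.74 (SE 0.13, limma adjusted p = 6.44e-17), and the next was also -1.74 (SE 0.12, limma adjusted p = 1.03e-17).

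**Figure D1:**
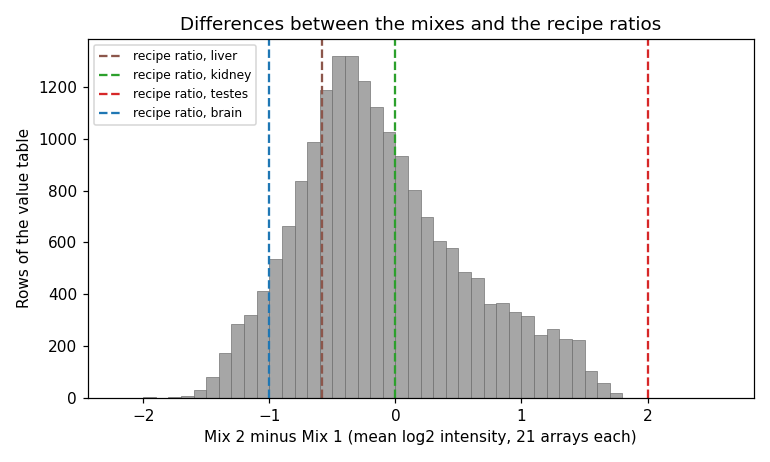
Histogram of the difference between mixes (Mix 2 minus Mix 1, mean log2 intensity of 21 arrays each) over 18625 rows, with dashed lines at the recipe ratios of the 4 tissues. The central 99% of rows run from -1.43 to 1.58.

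The recipe also bounds the differences. No row passed the test above the testes ratio (limma, 0 at adjusted p under 0.05, 1 at unadjusted p under 0.05), and 477 rows passed the test below the brain ratio, of 1317 with an estimate below it. Both counts depend on where the arrays are centred: median scaling gave 1 above and 6 below. The span of the central 99% of rows, which a common factor cannot alter, was 3.00 on the log2 scale (95% bootstrap interval 2.96 to 3.19), beside 3 between the testes and brain ratios of the recipe. The midpoint of the span lay 0.42 below that of the recipe (difference -0.42, interval -0.48 to -0.41), but -0.20 under median scaling. Both estimates lie near 1 end of their intervals. Drawing arrays with replacement adds noise to each row's difference and can widen the span, so these intervals may be biased. In the brightest 5% of tested rows, 932 rows, the span was 2.55. The cut of 99% was chosen after the values were seen, and all tested rows ran from -1.98 to 2.36. Another cut would give another span, so the closeness to 3 is no support for the recipe.

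Spread between arrays of a mix is itself a result for process controls. The median SD per row was 0.17 in Mix 1 and 0.20 in Mix 2 on the log2 scale, or coefficients of variation of 11.7% and 13.7%. It fell with level, from 0.24 and 0.28 in the dimmest quartile of tested rows to 0.12 and 0.13 in the brightest. The 3 arrays that stood apart were the lowest-numbered array of each mix and Mix 2 replicate 13. Their root mean square deviations from the mix median were 0.45 for Mix 1 replicate 1, 0.59 for Mix 2 replicate 1 and 0.60 for Mix 2 replicate 13. The other 20 arrays of Mix 1 lay between 0.16 and 0.27 and the other 19 of Mix 2 between 0.18 and 0.26.

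**Figure D2:**
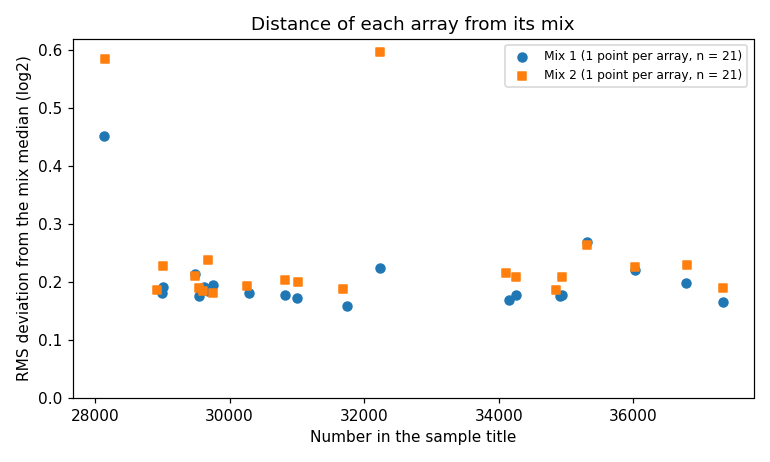
Root mean square deviation of each array from the median of its mix (log2, 18625 rows) against the number in the sample title, 1 point per array, 21 per mix. The first array of each mix (0.45 and 0.59) and Mix 2 replicate 13 (0.60) lie above the others, which reach 0.27.

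Gene lists are given by the rows listed under their members, with the limit on IDs above, and their values describe those rows and not the tissues. Medians are over the rows of a list. The permutation test and its p are of the list mean. Median scaling shifts the difference of every row by the same amount, so changes under it do not set a list apart from other rows. Of 16 rows listed under liver plasma proteins, 5 were higher in Mix 2 and 10 lower, with a median of -0.31; under median scaling it was -0.08 and the list no longer passed (permutation adjusted p = 0.305). Of 12 listed under liver enzymes and transporters, 3 were higher and 8 lower (median -0.22, mean -0.11, but a median of 0.01 under median scaling). That median was -0.03 under quantile normalization and -0.58 with the lowest 60% of rows left out. Of 18 kidney rows, 6 were higher and 8 lower (median -0.04, mean 0.01, permutation adjusted p = 0.781). Their median was 0.19 under median scaling (permutation adjusted p = 1.44e-05), 0.18 under quantile normalization (permutation adjusted p = 2.36e-05) and 0.24 with the lowest 60% of rows left out (permutation adjusted p = 1.08e-05). Of 5 rows of meiotic germ cells, 2 were higher and 2 lower; their median was -0.06 and their mean 0.31, opposite in sign, and the median was 0.17 under median scaling, 0.34 with the lowest 60% of rows left out and 0.07 within places 1 to 7. Of 13 spermatid rows, 8 were higher and 4 lower (median 0.43, mean 0.27). Of 9 rows of testis somatic cells, 3 were higher and 5 lower (median -0.50, but mean -0.12, permutation adjusted p = 0.000299, fry adjusted p = 0.827). That list no longer passed under quantile normalization (median -0.28, permutation adjusted p = 0.211), and its median was 0.31 with the lowest 60% of rows left out. Of 17 neuronal rows, 8 were higher and 5 lower (median 0.01, mean 0.07, permutation adjusted p = 0.00698). The neuronal median was -0.15 with no filter and -0.13 with all probes of a gene averaged. Under median scaling it was 0.24, under quantile normalization 0.15 and with the lowest 60% of rows left out 0.15. It ran from -0.01 to 0.05 with single arrays left out. It was below 0 without replicate 1, 5, 7, 9 or 11 of Mix 1. The same held without replicate 2, 9, 15, 16, 19 or 21 of Mix 2. The median therefore has no clear direction, while the list mean still passed without any single array. Of 12 glial rows, 4 were higher and 8 lower (median -0.46, but -0.23 under median scaling and -0.27 under quantile normalization). No median of the 3 testis lists came near 2.00. Of the 102 rows of the 8 tissue lists, 36 lay within 0.5 of their recipe ratio, or 26 after adding the offset of -0.42. The 2 liver lists gave 8 each of the 36, kidney 11, neurons 3, glia 5 and the testis lists 1, 0 and 0. The liver and kidney ratios lie on either side of the median of all rows, -0.21, and the share over all rows was not computed. Across the 102 rows the differences correlated with the recipe ratio at r = 0.17 (permutation p = 0.0894). Adjusted over the list alone, 15, 11, 14, 4, 12, 8, 13 and 12 rows of the 8 tissue lists passed, in the order given.

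The lists without a recipe ratio also held rows of both directions. Of 11 reference gene rows, 5 were higher and 5 lower (median 0.11, but -0.20 with no filter and -0.14 with all probes of a gene averaged). The median was 0.33 under median scaling, 0.18 under quantile normalization and 0.58 with the lowest 60% of rows left out. With single arrays left out this median ran from 0.051 without Mix 2 replicate 18 to 0.171 without Mix 1 replicate 18. Of 15 rows of blood and immune cells, 5 were higher and 8 lower (median -0.17, but 0.06 under median scaling, permutation adjusted p = 0.0520). Of 20 rows of tissues outside the recipe, 8 were higher and 9 lower (median -0.08, mean -0.01, permutation adjusted p = 0.703). Their median was 0.14 under median scaling (permutation adjusted p = 1.44e-05), 0.03 under quantile normalization (permutation adjusted p = 1.3e-05) and -0.15 with no filter (permutation adjusted p = 0.00332), and the list also passed with the lowest 60% of rows left out and with all probes of a gene averaged. Of 25 ribosomal protein rows, 13 were higher and 12 lower (median 0.09, but -0.08 with no filter, permutation adjusted p = 0.493), and of 57 respiratory chain rows, 14 were higher and 36 lower (median -0.31, mean -0.20, but a median of -0.08 under median scaling, permutation adjusted p = 0.0567). Adjusted over the list alone, 10, 13, 17, 25 and 50 rows passed. The mean of a list differed between mixes in 11 of 13 lists (permutation test, adjusted p under 0.05) and fry called 12, all but that of testis somatic cells, but neither sets a list against other rows. camera, which does, called 0 of 13 lists with a preset and 0 with an estimated correlation, and 1 list median, that of the spermatid rows, lay outside the range of 95% of 10000 random lists of like level (percentile 97.7), where 0.65 of 13 would by chance. That median was -0.12 with no filter (permutation adjusted p = 0.805) and 0.11 with all probes of a gene averaged. Within parts of the order, with fewer arrays, the permutation call was lost for testis somatic cells (places 1 to 7 and 15 to 21), neurons (1 to 7 and 8 to 14), reference genes (1 to 7) and liver enzymes and transporters (8 to 14).

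Change along the title number was asked because the series concerns the stability of arrays over time. In the fit over all arrays as fixed beforehand, 1010 rows had a positive slope and 799 a negative one (limma, adjusted p under 0.05). The median slope of these 1809 rows was 0.03 per 1000 in size, or 1.247-fold over the range of numbers. That fit counts the arrays of both mixes at 1 place as independent, although they deviated together (mean r = 0.27). With the 2 arrays of each place averaged, 3 rows passed (limma, 21 places, 3516 at unadjusted p under 0.05). In Mix 1 alone 1 row passed and in Mix 2 alone 3, with 2351 and 3194 at unadjusted p under 0.05 (limma). These fits hold fewer values than that over all arrays, so lost calls do not show that slopes are absent. The count over all arrays was 396 with centring on the kidney list and 2747 under median scaling. It rests in part on few arrays: without the lowest-numbered array of each mix 504 rows passed, and without Mix 2 replicate 13 as well 674. The slope differed between mixes in 0 rows (limma interaction, 438 at unadjusted p under 0.05). Across rows the slopes of the mixes correlated at 0.65, and at 0.50 without those 3 arrays. Because arrays of 1 place deviate together, such a correlation arises without any change along the number: with the numbers reassigned to places, both mixes together, it had a median of 0.32 (95% of 99 assignments 0.10 to 0.57), and 0.25 (0.07 to 0.46) without those arrays. None of the 99 was as high as 0.65, and 1 was as high as 0.50. This comparison was added after the values were seen.

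List means followed the title number in 0 of 26 relations within a mix (permutation test, adjusted p under 0.05; 3 at unadjusted p under 0.05), and differences between arrays of the same place in 0 of 13. Under median scaling 2 of the 26 passed by both Pearson and Spearman, both in Mix 2. They were the rows of liver enzymes and transporters (r = -0.66, permutation adjusted p = 0.0455, rho = -0.71) and the ribosomal protein rows (r = -0.62, permutation adjusted p = 0.0476, rho = -0.65). The respiratory chain rows in Mix 2 passed by Spearman alone (rho = -0.58, permutation adjusted p = 0.0484, Pearson permutation adjusted p = 0.0985). In the main scaling the lowest unadjusted Pearson p was that of the reference gene rows in Mix 1 (Pearson r = 0.50, permutation p = 0.0152, adjusted p = 0.309; Spearman rho = 0.46, permutation p = 0.0363; r = 0.49 without the 2 farthest arrays). In Mix 2 the reference gene rows had r = 0.46 (permutation p = 0.0357, adjusted p = 0.309), rho = 0.35 (permutation p = 0.118) and r = 0.46 without the 2 farthest arrays. The ribosomal protein rows in Mix 2 had r = -0.47 (permutation p = 0.0331, adjusted p = 0.309), rho = -0.50 (permutation p = 0.0232) and r = -0.62 without the 2 farthest arrays. Ratios of the rows listed as 3' and 5' ends of GAPDH, beta-actin and hexokinase differed between mixes in 0 of 3 tests and followed the title number in 0 of 6 (1 at unadjusted Pearson p under 0.05), with the same limit on what those rows hold. The 1 was the beta-actin ratio in Mix 2 (r = 0.49, permutation p = 0.0250, adjusted p = 0.150; rho = 0.55, permutation p = 0.0113; r = 0.62 without the 2 farthest arrays). The GAPDH ratio in Mix 2 had r = 0.37 (permutation p = 0.0975) and rho = 0.48 (permutation p = 0.0302), and r = 0.80 without the 2 farthest arrays.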

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

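Leaving out the arrays that stand apart, averaging the arrays of a place and all spans were chosen after seeing the data. The count of rows that differed between mixes, 16005, stayed within 1.5 times under all alternatives run (11017 to 20916); single arrays left out gave 15934 to 16112. Deposited scaling is the main one. Rows that passed the test above the testes ratio numbered 1 under median scaling, 5 with no filter and 1 with the floor at the 20th percentile. Rows that passed below the brain ratio numbered 6 under median scaling, and 30, 237 and 157 within places 1 to 7, 8 to 14 and 15 to 21, with fewer arrays; single arrays left out gave 453 to 504. The span was 3.11 and 3.10 in the first 2 of these parts of the order, and 2.98 to 3.03 without single arrays. Rows that followed the title number numbered 2747 under median scaling, 396 with centring on the kidney list, 1 and 3 in each mix alone, 3 with the 2 arrays of a place averaged, 504 without place 1 and 674 without place 1 and Mix 2 replicate 13. Single arrays left out gave 853 to 2468, with 853 without Mix 1 replicate 1, 921 without Mix 2 replicate 1 and 1036 without Mix 2 replicate 19. The cause was not tested. The slope differed between mixes in 0 rows under all alternatives. List means followed the number in 2 relations under median scaling.

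With the place as a replicate block, 16503 rows differed between mixes, 655 passed below the brain ratio and 11 lists differed. Arrays of 1 place deviated together (mean r = 0.27, other places -0.01), but not at every place (18 of 21 above 0.1, lowest -0.04). Own places correlated more than permuted ones (permutation p = 1e-05, the smallest possible), and 13 Mix 1 and 14 Mix 2 arrays correlated best with their own place. No label pairs the arrays, so this is a hint from the data.

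Under median scaling liver plasma proteins, the respiratory chain and blood and immune cells lost their list calls, and kidney and tissues outside the recipe gained one. Medians changed sign to 0.0054 for liver enzymes and transporters, 0.19 for kidney, 0.17 for meiotic germ cells, 0.056 for blood and immune cells and 0.14 for tissues outside the recipe. Under quantile normalization kidney (0.18) and tissues outside the recipe (0.025) changed sign and gained a call, and testis somatic cells lost theirs. With no filter the medians were -0.12 for spermatids and -0.076 for ribosomal proteins, both calls lost, and -0.15 for neurons and -0.20 for reference genes. With the lowest 60% left out they were 0.24 for kidney, which gained a call, 0.34 for meiotic germ cells and 0.31 for testis somatic cells. Meiotic germ cells gave 0.068 within places 1 to 7, and 0.31 as a mean over members, which the block alternative also uses. With all probes of a gene averaged, neurons gave -0.13 and reference genes -0.14. Tissues outside the recipe gained a call with no filter, with the lowest 60% left out and with probes averaged. Within the 3 parts of the order 6 list calls were lost. Kidney also changed sign, without a call, within places 8 to 14 and as a mean. Without single arrays the neuronal median ran from -0.011 to 0.049, with 11 changes of sign, and no list call changed.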

Other observations

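Tests of the row IDs, of a shared factor behind the first arrays, the reassignment of numbers by place, and the choice of control rows by their spread were made after the values were seen. Of 57 control rows, 24 had an SD within mixes above 0.7 on the log2 scale, and these rose and fell together from array to array (lowest r between any 2 rows 0.69, median 0.87). The number depends on that limit: 30 rows passed at 0.5, with a lowest r of -0.20, and 20 at 0.9. Their mean ranged over 9.39-fold in Mix 1 and 30.0-fold in Mix 2, where replicate 13 was lowest, and no tested row followed it beyond |r| = 0.66. Mix 1 and Mix 2 arrays of the same place had like values (Pearson r = 0.78, permutation p = 1e-05, the smallest possible; Spearman rho = 0.80, permutation p = 2e-05; r = 0.71 without the 2 farthest places). The IDs of these rows include those of GAPDH, beta-actin and hexokinase. Of the 24 control IDs that name dap, lys, phe or thr, 6 were among them.

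Rows listed under 1 gene symbol did not agree, and the 2 sets of control rows named for dap, and those for cre, were apart. The sets of the other control transcripts did not pass that test, but were apart in level by 0.91 to 6.98 on the log2 scale. That IDs and values stand in different row orders is a candidate explanation left untested: the correlation between rows of 1 symbol, -0.0171 and inside the range of shuffled IDs, is the pattern itself and adds no support. An outdated annotation of genes as the whole cause is argued against by control rows, whose IDs carry their own names, since the 2 sets named dap were apart by 1.284 in their difference between mixes; binding of a rat transcript by 1 of these sets was not tested. Noise is argued against by the correlation of 0.982 between alternate arrays. A single shift or reversal of the order is argued against by the best of 62198 shifts, 0.0844. Many other orders (sorted, hashed, and shifted within blocks of rows) were also looked at during exploration, and none gave a clear match. Their values were not kept, so they carry no weight here. Whether the order is at fault stays open, and no biological explanation was tested.

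The lowest-numbered array of each mix stood apart. After quantile normalization its deviation was still at least 1.54 times that of the highest array among those that did not stand apart (and above Mix 2 replicate 13 in Mix 2), which argues against scaling. Its deviation correlated little with the difference between mixes (0.11 in Mix 2, 0.08 in Mix 1). This argues against proportions of tissue shifted from 1 recipe towards the other. Other shifts of proportion need not follow that difference and were not tested. The deviations of these 2 arrays correlated at 0.732 across rows, above every other place (highest 0.62), consistent with a technical factor they share. No label names one, and no biological explanation was tested.

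Rows that followed the title number numbered 1809 when all arrays were counted as independent. With the numbers reassigned to places, both mixes together, 2 of 100 assignments gave as many, the real one included, and the highest other gave 3019 rows. Over the 39 arrays that did not stand apart, 674 rows passed, between the bounds written beforehand; 2 of 100 assignments gave as many, and the highest other gave 1448. The 1683 rows found after quantile normalization argue against array scaling as the whole cause. Centring on the kidney list left 396 and median scaling gave 2747. The centring rests on 18 rows, and whether it removes or adds differences between arrays was not tested. Whether scaling plays a part therefore stays open. When the arrays of a place were averaged, 3 rows passed and 3516 had an unadjusted p under 0.05 (limma). Whether rows follow the number, and what it stands for, remain open.

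Chance was examined with other splits. Of 100 splits of the arrays, 1, the real one, gave as many rows as the comparison of mixes (16005, highest other 11813; so high a count points to a structure of the samples, and how that split divided the mixes was not tested). For rows that passed below the brain ratio 1 of 100 gave as many (477, highest other 0), but the other splits hold both mixes in each group, so differences that far from 0 are not expected in them and this says nothing about chance. For the counts of 0 above the testes ratio and of 0 differences in slope, 100 of 100 give at least as many by construction, which says nothing about chance.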
